A study of Mus musculus with 9 samples.

How the data were processed

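Gene expression was measured by bulk sequencing of poly(A) RNA in 9 libraries of Panc02, a mouse pancreatic ductal adenocarcinoma cell line. The genotype labels formed 3 groups of 3 libraries each. The group called parental was the unedited line. KO_1E7 was a clone labelled as a knockout of VPAC2, the receptor for vasoactive intestinal peptide that is encoded by Vipr2. CRISPR_1G2 was a clone labelled as wild type after CRISPR. The series' design text counted both clones as coming from the knockout cells, which differs from the genotype label of CRISPR_1G2. The genotype labels were followed, and no sample was moved between groups. Group and replicate number were taken from the labels of each sample, so no library was left ungrouped.

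RNA was extracted from frozen pellets on a Qiasymphony instrument, and libraries were made by oligo-dT selection with the NEBNext Ultra II RNA kit, a kit that does not mark strand, per the labels' protocols. Reads were demultiplexed with bcl2fastq 2.17, aligned with STAR 2.5.2b to GRCm38 and counted per gene with featureCounts of Subread 1.5.2, per the submitters' processing notes, which also name DESeq2. The annotation release and the strand setting of the counting were not given in the sources used here. The values the authors deposited were raw counts of reads per gene, not normalized, in 1 table per sample and 1 table of the series. Both held 49671 genes and 92 spike-in controls and differed in 0 cells, and no column of per-sample values was left unused. Spike-in controls took between 0.344% and 0.820% of all counts and were left out of library sizes and tests. Gene symbols were those of the deposited series table, in which 174 genes had no symbol. Of the gene identifiers, 49412 were found in the GENCODE M21 annotation of GRCm38, 91.4% of them with the same chromosome, start and end and 99.9% overlapping. Coordinates were taken from the deposited tables. The sequence of the edited site was not analysed here. Counts without strand cannot tell a gene from its antisense partner, and genes with near-identical copies, such as Oas1a and Oas1g or Ifit1 and Ifit3b, may share reads, so their separate values are uncertain.

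Counts on genes ranged from 27898705 to 51878289 per library. Before averaging, the libraries were compared for duplicates: the chi-square statistic per gene between libraries of a group lay between 8.85 and 790, far above sampling noise, so all 9 were counted separately. Intervals given for pooled counts and their ratios are exact at the 95% level and cover counting error only, since reads carried no molecular identifiers. The limit of a count of 0 was taken as 3 counts. Nothing in the labels says that the 3 replicates of a group came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

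The comparisons, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined. Differential expression was tested in R 4.3.3 with the quasi-likelihood F-test of edgeR 4.0.16 in its robust form, on counts scaled by the trimmed mean of M-values (TMM), with all 9 libraries in 1 fit so that the groups shared the estimate of spread. Genes passing edgeR's expression filter by group numbered 15766. Pairs of groups were compared in 3 contrasts, and a further F-test asked for any difference among the groups. P-values were adjusted by Benjamini-Hochberg within each comparison and called at 0.05. Values per library are CPM computed here from TMM-scaled library sizes, and group values are mean ± SD of 3 libraries. Log2 fold changes carry their standard error (SE). A gene was counted against both references, or in both clones, when it was called in the same direction in both contrasts. An exact permutation test of 3 libraries against 3 cannot go below p = 0.1, so single genes were tested only in the model across genes. Principal components were computed on log2 CPM with a prior count of 2.

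Before the data were examined, 31 gene lists holding 738 gene symbols were written from textbook knowledge. For signalling and cell fate they were the VIP and PACAP receptor system, cAMP and PKA machinery, CREB-induced and immediate early genes, proliferation, p53 targets and apoptosis regulators. For immunity, cell state and matrix they were interferon-stimulated genes, MHC class I and antigen processing, chemokines and cytokines, epithelial markers, mesenchymal markers, collagen and matrix, and matrix proteases and inhibitors. For pathways and metabolism they were TGF-beta pathway and targets, Wnt pathway targets, YAP and TEAD targets, ERK pathway feedback genes, glycolysis and hypoxia, cholesterol synthesis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, ATF4 and amino acid response, endoplasmic reticulum chaperones and cytosolic ribosomal proteins. The last were markers of pancreatic duct, acinar, islet, immune, endothelial, fibroblast and erythroid cells. Some genes stand on several lists. Lists with at least 5 tested members, 27 of them, were tested against all other genes with camera of limma 3.58.1 at a preset correlation between genes of 0.01, adjusted over the 27 lists of a comparison, and again with an estimated correlation. Chromosomes were tested in the same way over the 3 comparisons and 20 chromosomes, adjusted over all of these together, and their shifts are given relative to the median log2 fold change of all genes. Those medians were -0.03 for KO_1E7 against parental, 0.02 for CRISPR_1G2 against parental and -0.03 for KO_1E7 against CRISPR_1G2.

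The rule for named genes took, per comparison, called genes with an absolute log2 fold change of at least 1, a mean of at least 5 CPM, a symbol that is not a predicted name and no overlap between the libraries of the groups compared. Of these it took the 10 highest and the 10 lowest. For KO_1E7 against both references and for both clones against parental it took the 8 highest and 8 lowest by the smaller of the pair of fold changes. In each list it took up to 4 members with the smallest adjusted p. Vipr2, Vip, Adcyap1, Vipr1, Adcyap1r1 and the genes directly before and after Vipr2 were always named. Values of other genes, given mostly per library, belong to genes chosen after their values were seen, and this is said where they appear. Some results that the rule would name are not reported.

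Groups shared replicate numbers, so the correlation across genes of same-numbered libraries' deviations from their group means was checked before any blocked fit was compared. Between parental and CRISPR_1G2 it was 0.243, 0.469 and 0.647 for the 3 numbers, all over 0.1. The numbers were therefore taken to pair these libraries, a pairing from the data, as the labels do not say what a number marks. Pairs with different numbers also lay over 0.1, parental 2 with CRISPR_1G2 1 at 0.540 and parental 1 with CRISPR_1G2 2 at 0.136. Deviations cancel within a group, so the strong pair numbered 3 tends to raise all correlations among libraries 1 and 2. Passing 0.1 thus does not show that libraries 1 and 2 pair by number. KO_1E7 libraries were not paired with either group, with correlations of -0.00, 0.06 and 0.15 to parental and -0.05, 0.13 and 0.07 to CRISPR_1G2. The deposited names of the tables also carry dates or the word NSG, whose meaning is not given in the sources used here, and these served only as alternative terms. Parental 2 and CRISPR_1G2 1 share a date, and the libraries numbered 3 share the word. Between parental and CRISPR_1G2 the highest correlations, 0.647 and 0.540, thus belonged to libraries with a shared word or date.

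Alternatives tried were DESeq2 1.42.0, DESeq2 size factors in edgeR, no filter, a filter of at least 1 CPM in 3 libraries, and fits with only the pair of groups compared. Further alternatives were the replicate number as a block, a term for the word NSG, the date or word as a factor, and an estimated correlation for lists and chromosomes. Also tried were the third library of each group left out for lists, a window of 5 instead of 2 Mb around Vipr2, and each library left out in turn. A further 3 were chosen after seeing the data, namely leaving out parental 3 and CRISPR_1G2 3, leaving out KO_1E7 2 as well, and limma's voom with quality weights. The recomputation of lists, chromosomes and genes near Vipr2 without each library, and of lists with DESeq2 size factors, was also added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

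The tests were tested on simulated data drawn from the means and library sizes of the real libraries with genes changed by 1.5, 2 or 4-fold. For KO_1E7 against parental, 0%, 10.4% and 53.0% of the genes changed by these folds were recovered among 15487 genes. For CRISPR_1G2 against parental, 1.49%, 5.97% and 63.6% were recovered among 15442 genes, and for KO_1E7 against CRISPR_1G2 2.99%, 13.4% and 59.1% among 15415 genes. False calls numbered 2 in each. In a simulation of KO_1E7 against parental with 15454 genes, the 1 list moved by 1.5-fold and the 1 chromosome moved by 1.25-fold passed, and 0 unmoved lists or chromosomes did. The count tests at this depth and spread therefore miss most changes near 2-fold. Each gene was drawn independently, so the simulations held no correlation between genes and no deviations shared between libraries. Their low numbers of false calls need not hold for the real libraries, where other splits passed up to 13 lists and called up to 817 genes.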

Results

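RNA was sequenced from Panc02, a mouse pancreatic ductal adenocarcinoma line grown in DMEM with 10% serum and no further treatment. The series asked what VPAC2 does for the growth of pancreatic cancer cells. VPAC2, the product of Vipr2, is a G protein-coupled receptor for vasoactive intestinal peptide (VIP) and for PACAP, and it signals mainly through cAMP. There were 9 libraries, 3 each of the parental line, of the clone labelled VPAC2 knockout (KO_1E7) and of the clone labelled wild type after CRISPR (CRISPR_1G2). Read counts on genes were 35877425, 36643451 and 41305893 in parental 1, 2 and 3, 34857095, 51878289 and 32907269 in KO_1E7 1, 2 and 3, and 27898705, 31748396 and 30041969 in CRISPR_1G2 1, 2 and 3. Between 14111 and 16179 genes had at least 10 counts in a library, and 15766 genes were tested.

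Vipr2 transcripts, the target of the edit, were rare in every library. Vipr2 (ENSMUSG00000011171, plus strand of chromosome 12, 116077726 to 116146261 on GRCm38) had 6, 3 and 12 counts in parental 1, 2 and 3, 1, 2 and 1 in KO_1E7 1, 2 and 3, and 1, 13 and 12 in CRISPR_1G2 1, 2 and 3. Pooled over each group, this was 0.193 CPM in parental (95% interval of counting error 0.119 to 0.295), 0.0329 CPM in KO_1E7 (0.00896 to 0.0842) and 0.283 CPM in CRISPR_1G2 (0.185 to 0.414). Pooled Vipr2 counts per library size were 5.87 times higher in parental than in KO_1E7 (interval 1.98 to 23.5) and 8.59 times higher in CRISPR_1G2 than in KO_1E7 (2.98 to 33.9). Against the spread between replicates, Vipr2 did not pass in the main edgeR fit. Its log2 fold change was -2.45 ± 0.97 (SE, n = 3 per group, adjusted p = 0.155) in KO_1E7 against parental. It was -2.95 ± 0.95 (adjusted p = 0.0675) in KO_1E7 against CRISPR_1G2 and 0.50 ± 0.75 (adjusted p = 0.955) in CRISPR_1G2 against parental. CRISPR_1G2 1, with 1 count, lay as low as the KO_1E7 libraries, and without it Vipr2 passed in KO_1E7 against CRISPR_1G2 (adjusted p = 0.0368, where all settings gave 0.0368 to 0.202). In that comparison Vipr2 also passed narrowly with DESeq2 (adjusted p = 0.0458) and in edgeR with a term for the word NSG (0.0481). A knockout made by a small insertion or deletion need not lower the count of a transcript, so these values neither show nor exclude the edit in any library. Gm20658, an antisense gene inside the span of Vipr2, had 26 counts over all libraries and cannot be told apart from Vipr2 without strand.

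The ligand gene Vip had 5, 1 and 19 counts in the parental libraries, 0 in each KO_1E7 library and 1, 2 and 12 in the CRISPR_1G2 libraries, and it was too low to test. The genes of PACAP (Adcyap1) and of the other receptors (Vipr1, Adcyap1r1) had at most 2 counts in any group. Of the 12 genes of the VIP and PACAP receptor system, 3 were tested (Vipr2, Ramp1 and Ramp3), too few for a list test. In edgeR with all libraries 0 passed in any comparison, and over the list alone Vipr2 was lower in KO_1E7 against CRISPR_1G2. Zfp386, the gene directly before Vipr2 (116047724 to 116063360), stood at 27.96 ± 2.41, 34.3 ± 3.46 and 27.9 ± 0.24 CPM in parental, KO_1E7 and CRISPR_1G2, with a log2 fold change of 0.29 ± 0.13 (adjusted p = 0.210) in KO_1E7 against parental. Gm44372 and Gm23732, the small RNA genes directly after it, had 0 and 1 count over all libraries. Within 2 Mb of Vipr2, 7 other genes were tested. By edgeR 0 of them passed in KO_1E7 against parental, where 2 had an unadjusted p below 0.05, and 0 passed in CRISPR_1G2 against parental, where 0 did. Ncapg2, a condensin subunit gene, passed in KO_1E7 against CRISPR_1G2 (0.58 ± 0.15, adjusted p = 0.0356). That call ended without parental 1 or without any 1 of the 6 KO_1E7 and CRISPR_1G2 libraries, and 1 gene passed in KO_1E7 against parental without CRISPR_1G2 3.

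**Figure D1:**
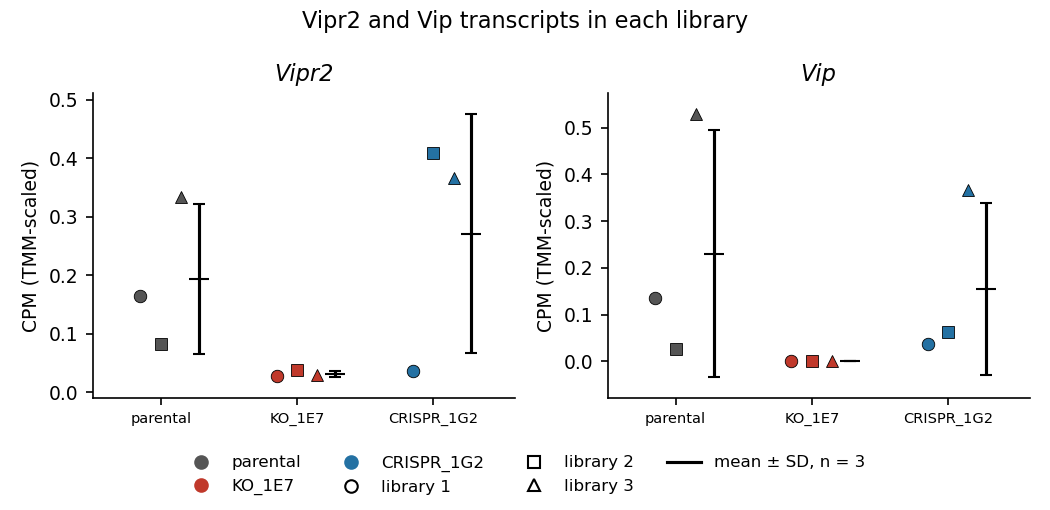
CPM of Vipr2 and Vip in each of the 9 libraries, with points for libraries and black bars for the mean and SD of the 3 libraries of parental, KO_1E7 and CRISPR_1G2. Pooled Vipr2 counts stood at 0.193, 0.0329 and 0.283 CPM, and Vip had 0 counts in every KO_1E7 library.

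Several libraries stood apart from others of their group. The first principal component held 42.7% of the variance and placed parental 1, 2 and 3 at -9.88, 6.48 and -58.2, KO_1E7 1, 2 and 3 at 66.9, 47.1 and 68.3, and CRISPR_1G2 1, 2 and 3 at -15.1, -19.2 and -86.3. In parental 3, 23.01% of gene counts lay on ribosomal RNA related genes (15.3% on CT010467.1 alone), against 1.12% in CRISPR_1G2 3 and 0.969% to 1.79% in the other 7 libraries. Parental 3 and CRISPR_1G2 3 had high levels of targets of p53, the stress-activated tumour suppressor, and low levels of cholesterol synthesis genes, as these genes chosen after their values were seen show. Mdm2 stood at 1857 and 3910 CPM in these libraries against 646 to 1173 in the other 7, Cdkn1a at 189 and 480 against 31.8 to 72.9, and Hmgcs1 at 51.4 and 71.9 against 212 to 599.9. KO_1E7 2 lay between its group and the rest at other genes chosen the same way. Imprinted Igf2 stood at 5.54, 80.7 and 2.81 CPM in KO_1E7 1, 2 and 3 against 230.1 to 344 in parental, and Rhox5 at 6.36, 91.3 and 4.48 against 194 to 344.

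**Figure D2:**
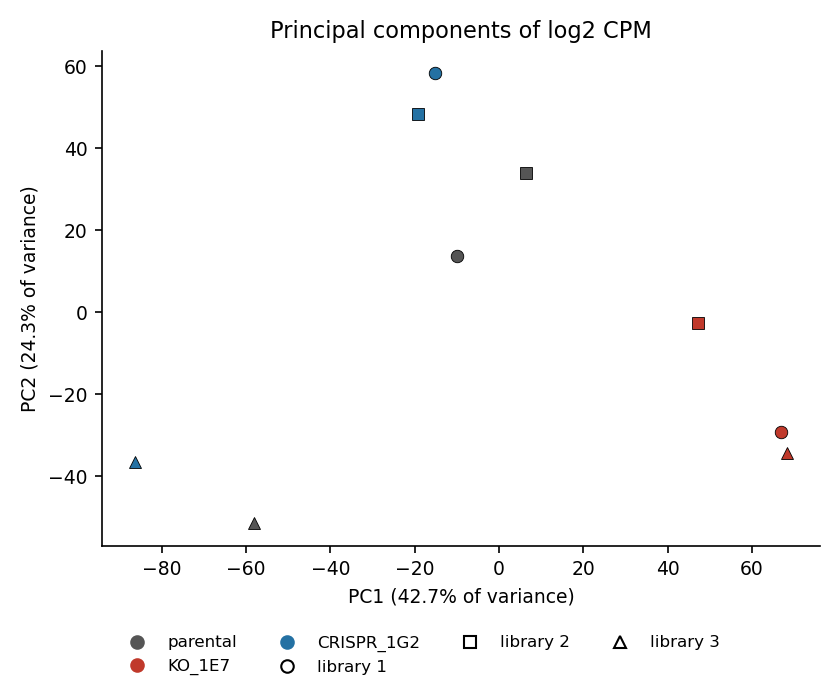
The 9 libraries on the first and second principal components of log2 CPM (42.7% and 24.3% of the variance), coloured by group and with a symbol for each replicate number. KO_1E7 libraries lie at 47.1 or above on the first component, and parental 3 and CRISPR_1G2 3 at -58.2 and -86.3.

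KO_1E7 against parental asked what differed between the clone labelled knockout and the line it came from. KO_1E7 was the only clone labelled knockout, and its libraries repeat that clone. In every comparison with KO_1E7, effects of losing VPAC2 and other differences of this clone cannot be told apart. Thbs2, which encodes the secreted matrix protein thrombospondin-2 (ENSMUSG00000023885, chromosome 17, 14665500 to 14694262), rose from 305 ± 36.1 CPM in parental to 2937 ± 403 in KO_1E7 (SD, n = 3 each), a log2 fold change of 3.27 ± 0.28 (adjusted p = 0.00276). The matrix protease stromelysin-1 gene Mmp3 (chromosome 9, 7445822 to 7455975) rose from 1.86 ± 0.16 to 73.2 ± 63.9 CPM (5.30 ± 0.92, adjusted p = 0.0194). Trp63, which encodes the basal epithelial transcription factor p63 (chromosome 16, 25683763 to 25892102), rose from 1.02 ± 0.04 to 27.4 ± 18.2 CPM (4.74 ± 0.64, adjusted p = 0.0119). Mmp3 and Trp63 were far lower in KO_1E7 2 (7.98 and 6.67 CPM) than in KO_1E7 1 (76.1 and 35.0) and 3 (136 and 40.5), yet above every parental library. Hspg2, which encodes the basement membrane proteoglycan perlecan (chromosome 4, 137468769 to 137570630), fell from 18.7 ± 1.41 to 2.27 ± 0.68 CPM (-3.05 ± 0.26, adjusted p = 0.00276).

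By the fixed rule, the other genes with the largest rises were Gdpd2 (log2 fold change 4.85), the membrane repair gene Dysf (4.19), Selenbp1 (3.398), the transcription factor gene Sox13 (3.39), Casp12 (3.15), the basal keratin gene Krt15 (3.12) and Ucp2, which encodes a mitochondrial uncoupling protein (3.00). Dysf rose from 0.902 ± 0.28 to 16.5 ± 4.21 CPM and Krt15 from 1.83 ± 0.34 to 15.99 ± 4.84 CPM. The largest falls were of the interferon-induced genes Cmpk2 (-4.46), Igtp (-3.37) and Oas1a (-3.31), of Igf2os (-4.24), Zfp503 (-3.91), Prickle2 (-3.90), Zfp850 (-3.86), the ubiquitin ligase gene Uhrf2 (-3.61), the integrin gene Itgb7 (-3.58) and Plac8 (-3.13). Plac8 fell from 264 ± 32.4 to 30.1 ± 23.5 CPM, with KO_1E7 2 at 57.2 CPM above KO_1E7 1 and 3 at 17.6 and 15.3. Igf2os runs antisense to Igf2, whose reads cannot be told from its own without strand. In all, 401 genes were higher and 453 lower by edgeR at an adjusted p of 0.05, 211 and 217 of them by at least 2-fold. With DESeq2 there were 1091 higher and 1267 lower. All 854 genes called by edgeR showed no overlap between the libraries of the groups, as did 34.4% of all genes tested, where chance gives 10%.

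A list is said to have moved where it passed the list test at the preset correlation. With an estimated correlation 0 lists passed in any comparison, and other splits of the libraries passed as many lists or more. Of 38 interferon-stimulated genes 6 passed, all lower (24 when adjusted over the list alone). All 38 estimates were negative with a median log2 fold change of -1.97, and the list test gave an adjusted p of 1.66e-11, or adjusted p = 0.818 with an estimated correlation. Among these antiviral genes Oas1g changed by -4.69 ± 0.77 (adjusted p = 0.0170), Ifit3b by -2.50 ± 0.47 (0.0250) and Ifit1 by -2.34 ± 0.46 (0.0290). Parental 3 carried much of the level of this list: summed CPM of interferon-stimulated genes was 738, 461 and 1748 in parental 1, 2 and 3 and 484, 454 and 408 in KO_1E7 1, 2 and 3. With parental 3 and CRISPR_1G2 3 left out, a setting chosen after seeing the data, the median for interferon-stimulated genes was -1.05, 10 were lower and the adjusted p was 0.000313.

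Cholesterol synthesis genes moved up as a list (adjusted p = 0.000968, or adjusted p = 0.818 with an estimated correlation). All 24 estimates were positive, with a median of 0.79 and 0 of 24 single genes past the threshold in edgeR, also when adjusted over the list alone. The sterol enzyme gene Msmo1 stood at 1.21 ± 0.56 (adjusted p = 0.233). Summed CPM for cholesterol synthesis was 4338, 6716 and 1465 in parental 1, 2 and 3 against 7857, 6137 and 7737 in KO_1E7. The low library was parental 3, and without it the adjusted p was 0.0948. Mitochondrially encoded mRNAs also moved up (adjusted p = 0.0246, or adjusted p = 0.818 with an estimated correlation), with 13 of 13 estimates positive, a median of 0.40 and 0 of 13 called, also over the list alone. The gene mt-Co1 stood at 8055 ± 341 CPM in parental and 11175 ± 414 in KO_1E7 (0.47 ± 0.13, adjusted p = 0.0758). Without parental 3, the adjusted p for mitochondrially encoded mRNAs was 0.105, and without the third library of each group it was 0.208. With parental 3 and CRISPR_1G2 3 left out it was 0.114, and with KO_1E7 2 out as well 0.0943.

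Epithelial markers moved down (adjusted p = 0.0194, or adjusted p = 0.488 with an estimated correlation), with 2 of 22 lower (4 when adjusted over the list alone) and a median of -0.47. Summed CPM of epithelial markers was 1981, 2073 and 1285 in parental 1, 2 and 3 and 1299.7, 2060 and 1254 in KO_1E7 1, 2 and 3, so KO_1E7 2 lay at the level of parental 1 and 2, and parental 3 at that of KO_1E7 1 and 3. The tight junction gene Cldn7 fell from 12.6 ± 3.87 to 3.41 ± 0.49 CPM (-1.89 ± 0.29, adjusted p = 0.0156) and the simple keratin gene Krt7 from 25.9 ± 7.06 to 4.58 ± 0.67 CPM (-2.50 ± 0.51, adjusted p = 0.0323). Of 18 mesenchymal markers, Sparc (0.84 ± 0.11), Prrx1 (3.224 ± 0.45) and Twist2 (2.93 ± 0.43) were higher and 0 lower, the same counts when adjusted over the list alone. The list itself did not pass (adjusted p = 0.0552). ERK pathway feedback genes moved down (adjusted p = 0.0244, or adjusted p = 0.818 with an estimated correlation). Epha4 (-2.88 ± 0.52) and the ERK phosphatase gene Dusp5 (-1.63 ± 0.34) were lower of 20, and 1 was higher and 5 lower when adjusted over the list alone. The adjusted p of ERK pathway feedback genes was 0.0538 without KO_1E7 1, 0.0702 without KO_1E7 3 and 0.172 without the third library of each group. The list ATF4 and amino acid response moved down (adjusted p = 0.0239, or adjusted p = 0.818 with an estimated correlation). Stc2 (-1.49 ± 0.31) and Cebpb (-1.12 ± 0.25) were lower of 27, both also over the list alone. For ATF4 and amino acid response the adjusted p was 0.253 without parental 1, 0.141 without KO_1E7 1 and 0.0730 without the third library of each group. It was 0.0826 with parental 3 and CRISPR_1G2 3 left out and 0.0570 with KO_1E7 2 out as well.

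Among genes of the receptor's own signalling, 2 of 32 in cAMP and PKA machinery were higher and 2 lower (3 and 2 when adjusted over the list alone), and the list test did not pass (adjusted p = 0.364). Adcy7, an adenylyl cyclase gene, rose from 34.2 ± 4.11 to 103 ± 18.5 CPM (1.59 ± 0.26), and the cAMP phosphodiesterase gene Pde4d rose by 1.43 ± 0.24. Crtc3, a CREB coactivator gene, fell by 0.84 (SE 0.13). Rapgef4, which encodes the cAMP sensor EPAC2, fell by 4.78 (SE 1.06), with 105 counts over the parental libraries and 4 over KO_1E7, a ratio of 29.4 (interval 11.1 to 109.7). CREB-induced and immediate early genes had 1 of 23 higher (Pde4d, also over the list alone) and an adjusted p of 0.830, with a median of -0.06 although the test pointed up. With parental 3 and CRISPR_1G2 3 left out, CREB-induced and immediate early genes had 4 higher and an adjusted p of 0.0269, upward.

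Apart from immune cell markers, which passed and are given below with other cell types, the remaining lists did not pass in this comparison. Collagen and matrix had 3 of 39 higher (Thbs2, Bgn, Fbln1) and 2 lower (Hspg2, Fbln2), 7 and 6 when adjusted over the list alone, with an adjusted p of 0.932 and a median of -0.26 but a mean of 0.02. Matrix proteases and inhibitors had Mmp3 and Adamts4 higher and Plaur lower of 26 (2 and 2 over the list alone, adjusted p = 0.507). The p53 targets had Tnfrsf10b higher (0.61 ± 0.12) and Perp (-1.57 ± 0.34) and Bax (-0.55 ± 0.13) lower of 23 (1 and 4 over the list alone, adjusted p = 0.0667). Cytosolic ribosomal proteins had 5 of 36 lower (2 higher and 8 lower over the list alone, adjusted p = 0.154), among them Rps16, Rpl18, Rpl28 and Rps19 on chromosome 7. Wnt pathway targets had Notum and Dkk2 higher and Znrf3 lower of 12 (3 and 4 over the list alone, adjusted p = 0.830). Apoptosis regulators had Bmf higher and Bax lower of 21 (3 and 1 over the list alone, adjusted p = 0.739). Chemokines and cytokines had Cxcl15 higher of 25 (3 and 2 over the list alone, adjusted p = 0.932), and endoplasmic reticulum chaperones had Herpud1 higher of 20 (1 and 0, adjusted p = 0.0788). One lower gene each was called in the TGF-beta pathway and targets (Pmepa1 of 30, adjusted p = 0.739), glycolysis and hypoxia (Pfkfb3 of 29, adjusted p = 0.364) and nuclear-encoded oxidative phosphorylation (Cox6b1 of 40, adjusted p = 0.219). Over the list alone the last had 0 and the others 1. In proliferation (38 genes, adjusted p = 0.0745), MHC class I and antigen processing (21, 0.987) and YAP and TEAD targets (16, 0.298), 0 genes passed in edgeR or over the list alone. The test pointed against the sign of the mean in cAMP and PKA machinery (mean -0.15) and MHC class I and antigen processing (mean -0.14). It pointed against that of the median in apoptosis regulators (median -0.10) and the TGF-beta pathway and targets (median -0.00).

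**Figure D3:**
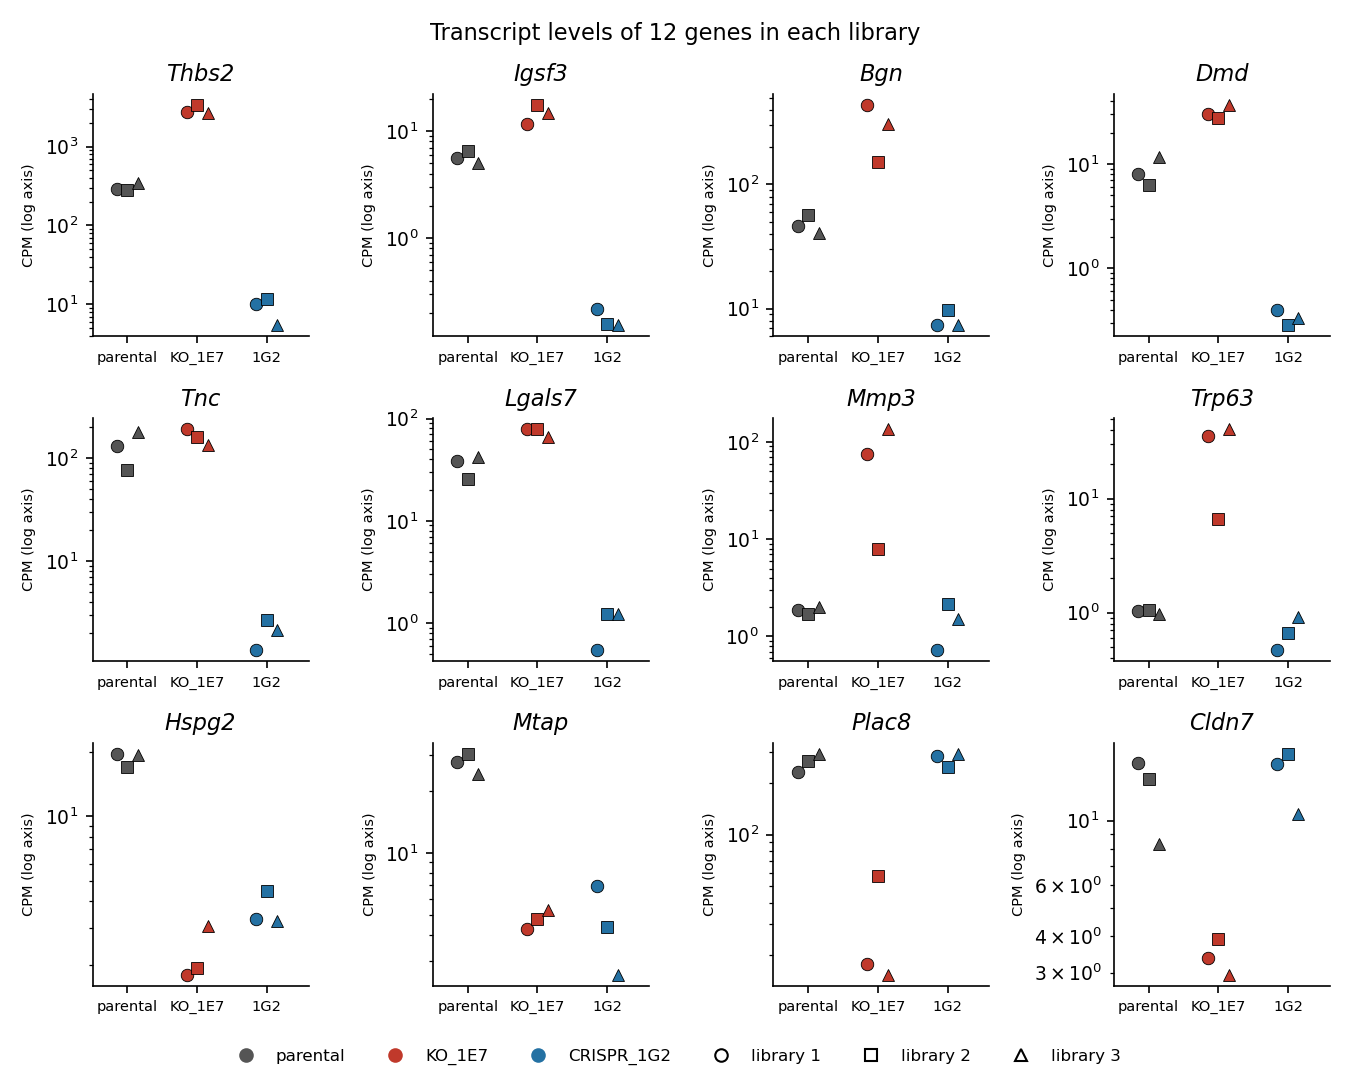
CPM of 12 genes in each of the 9 libraries on a log axis, with 1 symbol per replicate number (1G2 for CRISPR_1G2). Thbs2 averaged 305 CPM in parental, 2937 in KO_1E7 and 9.06 in CRISPR_1G2.

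Genes of whole chromosomes shifted together in KO_1E7. Relative to the median of all genes, the 1240 tested genes of chromosome 7 had a median log2 fold change of -0.42 against parental, with 15 higher and 133 lower (adjusted p = 2.65e-13). The 892 genes of chromosome 8 had one of 0.34, with 76 higher and 9 lower (adjusted p = 3.24e-09). Chromosomes 16 (-0.35), 2 (-0.17) and 11 (-0.15) were also lower, and chromosomes 14 (0.31), 13 (0.16) and 9 (0.16) higher, so that 8 of 20 passed, all 8 also with an estimated correlation. Chromosome 13 no longer passed without parental 2 (adjusted p = 0.0718). Another split of the KO_1E7 and parental libraries passed 10 chromosomes, so the number passing cannot be told from that of other arrangements. Crtc3, Bax, Cox6b1 and Plaur, all lower, lie on chromosome 7.

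**Figure D4:**
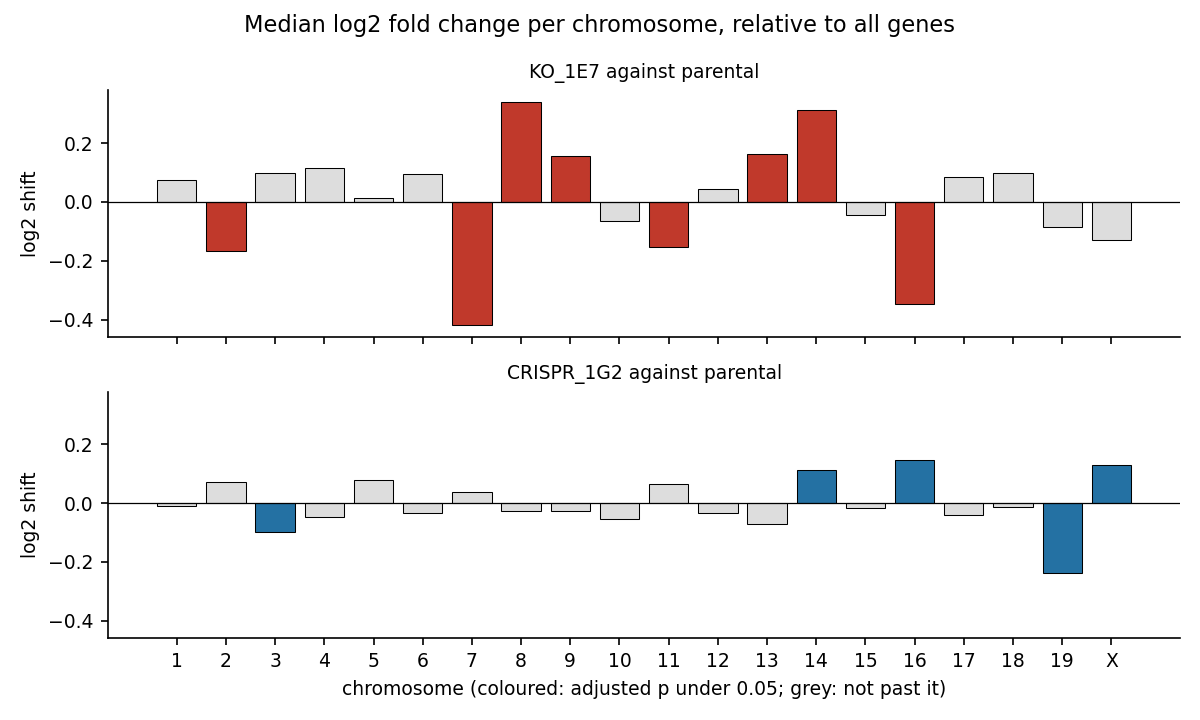
Median log2 fold change of the tested genes of each chromosome relative to that of all genes, as bars for KO_1E7 and for CRISPR_1G2 against parental, coloured where the adjusted p was below 0.05. Chromosome 7 lay at -0.42 and chromosome 8 at 0.34 in KO_1E7 against parental.

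The number of called genes in KO_1E7 against parental depended on single libraries. Without parental 1, 2 or 3 it was 113 higher and 55 lower, 141 and 209, or 151 and 188. Without KO_1E7 1, 2 or 3 it was 30 and 19, 240 and 354, or 16 and 8. Without CRISPR_1G2 1, 2 or 3, which take part in the filter, the scaling and the spread, it was 192 and 193, 182 and 181, or 953 and 1045. Of 64 called genes followed through these fits, Dysf, Thbs2 and Hspg2 passed in all 9. Without KO_1E7 3, 3 passed, 8 without KO_1E7 1, 17 without parental 1 and 35 to 42 without parental 2, parental 3, KO_1E7 2, CRISPR_1G2 1 or CRISPR_1G2 2, and 0 changed sign.

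KO_1E7 against CRISPR_1G2 asked what differed between the clone labelled knockout and a clone that had gone through the same editing but was labelled wild type. If CRISPR_1G2 comes from the knockout cells, as the design text of the series counts it, the contrast is between clones of edited cells and carries no wild-type reference. More genes were called than against parental. Thbs2 stood at 2937 ± 403 CPM in KO_1E7 and 9.06 ± 3.26 in CRISPR_1G2 (log2 fold change 8.34 ± 0.36, adjusted p = 2.42e-05). Tnc, which encodes the matrix protein tenascin C (chromosome 4, 63959785 to 64047015), stood at 162 ± 28.6 and 2.07 ± 0.65 CPM (6.29 ± 0.41, adjusted p = 0.000178). Igsf3, Dmd and Lgals7 were higher in KO_1E7 by 6.36 ± 0.30, 6.54 ± 0.33 and 6.21 ± 0.35, and Sox13, Foxp2, Mmp3 and the alarmin gene Il33 by 7.04, 6.63, 5.64 and 5.48. The lowest were Zfp503 (-4.80), Zfp850 (-4.47), the casein gene Csn3 (-4.03), Igf2os (-4.00), Zfp110 (-3.98), Adgra2 (-3.98), the growth factor gene Pdgfb (-3.87), Itgb7 (-3.82), the ephrin receptor gene Epha4 (-3.81) and Renbp (-3.77). Zfp110 and Renbp stood at 9.23 and 7.90 CPM in KO_1E7 2 and below 1 CPM in KO_1E7 1 and 3, against 31.6 to 82.8 CPM in CRISPR_1G2. In all 901 genes were higher and 1109 lower, 529 and 528 of them by at least 2-fold. All 2010 showed no overlap between groups, as did 38.6% of all genes where chance gives 10%.

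Epithelial markers moved down in KO_1E7 relative to CRISPR_1G2 (adjusted p = 0.00313, or adjusted p = 0.480 with an estimated correlation), with 6 of 22 lower (7 over the list alone) and a median of -0.83. The 6 were Cldn7 (-2.07 ± 0.29), Krt7 (-3.23 ± 0.53), the repressor gene Ovol1 (-3.48 ± 0.71), the splicing regulator gene Esrp1 (-3.35 ± 0.79), the adhesion gene Epcam (-2.83 ± 0.68) and Ocln (-1.55 ± 0.40). Esrp1, Epcam and Ocln stood higher in KO_1E7 2 (5.87, 3.43 and 6.76 CPM) than in KO_1E7 1 (0.707, 1.02 and 1.95) and 3 (0.687, 0.746 and 3.34). Summed CPM of epithelial markers was 1937, 2166 and 930 in CRISPR_1G2 1, 2 and 3 against 1299.7, 2060 and 1254 in KO_1E7, so the lowest library was CRISPR_1G2 3. Mesenchymal markers had Sparc (1.17 ± 0.11), Twist2 (4.82 ± 0.51), Pdgfrb (1.83 ± 0.32) and Prrx1 (2.01 ± 0.41) higher of 18 and Cdh2, the N-cadherin gene, lower (-1.55). The counts over the list alone were the same (adjusted p = 0.132). The p53 targets moved down (adjusted p = 0.000970, or adjusted p = 0.996 with an estimated correlation) with a median of -1.35. Perp (-2.21 ± 0.35), Phlda3 (-2.03 ± 0.53), Aen (-1.48 ± 0.36), Bax (-0.77 ± 0.13) and Ddb2 (-0.71 ± 0.17) were lower of 23 (7 over the list alone). CRISPR_1G2 3 carried much of the level of this list, with summed CPM of p53 targets of 2231, 2640 and 9034 in CRISPR_1G2 1, 2 and 3 against 1772, 1809 and 1778 in KO_1E7. Without CRISPR_1G2 3 the median for p53 targets was -0.41 and the adjusted p 0.104. With parental 3 left out too, 10 of the 23 were lower and the adjusted p was 0.00324.

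In cAMP and PKA machinery, 6 of 32 were higher in KO_1E7 than in CRISPR_1G2 and 3 lower (8 and 4 over the list alone, adjusted p = 0.564). Among them Adcy7 (2.21 ± 0.27), Crtc2 (0.47 ± 0.10) and Pde4d (1.08 ± 0.23) were higher and Crtc3 (-0.84 ± 0.13) and Rapgef4 (-4.42 ± 1.07) lower. CREB-induced and immediate early genes had Pde4d and Egr1 higher of 23 (2 over the list alone, adjusted p = 0.842). Collagen and matrix had 7 of 39 higher and 6 lower (7 and 12 over the list alone, adjusted p = 0.725). Thbs2, Tnc, Bgn, Col8a1, Fbln1 and Col1a2 (3.67 ± 1.03) were higher and Col1a1 (-1.59 ± 0.43) lower. The Col1a1 call was lost in 14 of 21 settings and that of Col1a2 in 11. Matrix proteases and inhibitors had 2 of 26 higher and 4 lower (adjusted p = 0.842), with Adamts4 (2.89) and Mmp3 higher and Adam19 (-3.05) and the urokinase receptor gene Plaur (-1.44) lower. Cytosolic ribosomal proteins had Rps6 (0.80) and Rpsa (0.82) higher and 6 lower of 36, among them Rps16 and Rpl28 (adjusted p = 0.986). Chemokines and cytokines had Il33, Cxcl15 and Il11 higher and Cxcl16 lower of 25. Wnt pathway targets had 2 higher and 3 lower of 12, with Notum and Dkk2 higher and Znrf3 and Wnt7b lower. Interferon-stimulated genes had Oas1g and Cmpk2 lower of 38 (0 over the list alone), with a median of -0.75 and an adjusted p of 0.0866. In all 2 of 27 lists passed, and the other 25 had adjusted p-values of at least 0.0866. The test pointed against both median and mean in cAMP and PKA machinery, CREB-induced and immediate early genes and chemokines and cytokines. It pointed against the median in collagen and matrix (-0.37), glycolysis and hypoxia (0.09) and ATF4 and amino acid response (0.06).

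By chromosome, 11 of 20 passed, 10 of them with an estimated correlation. Chromosomes 7 (-0.50, with 24 higher and 274 lower), 16 (-0.49) and 8 (0.37) lay farthest from the median of all genes. Chromosome 14 no longer passed without KO_1E7 2 (adjusted p = 0.0675) or CRISPR_1G2 2 (0.0508). Chromosome X no longer passed without KO_1E7 1 (0.0663) or CRISPR_1G2 1 (0.0599) or with an estimated correlation (0.344). The count of lower genes fell to 661 without parental 1. Higher and lower counts were 303 and 250 without KO_1E7 1, 273 and 180 without KO_1E7 3, 397 and 550 without CRISPR_1G2 1 and 417 and 532 without CRISPR_1G2 2. Of 75 called genes followed, 36 passed in all 9 fits that left out a library, among them Thbs2, Tnc, Dmd, Mmp3, Trp63, Plac8, Cldn7 and Adcy7. The fewest (37) passed without KO_1E7 3, and 0 changed sign.

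Genes called in the same direction in KO_1E7 against both references numbered 342 higher and 364 lower by edgeR, and more by DESeq2, as given with the alternatives below. By the fixed rule these were led by Mmp3, Gdpd2, Trp63, Dysf, Selenbp1, Sox13, Thbs2 and Casp12 among the higher and Igf2os, Zfp503, Zfp850, Prickle2, Itgb7, Cmpk2, Uhrf2 and Plac8 among the lower. The smaller of each pair of log2 fold changes was 5.30 for Mmp3, 4.74 for Trp63 and -3.13 for Plac8 (chromosome 5, 100553725 to 100572245), which stood at 264 ± 32.4 CPM in parental, 30.1 ± 23.5 in KO_1E7 and 276 ± 24.7 in CRISPR_1G2. Fold changes of the pair of contrasts correlated across genes at 0.794 with a covariance of 0.683, where simulated unchanged groups gave 0.492 and 0.101. The simulation drew all libraries anew and each gene apart from a common mean, so sharing a group gives such a correlation by itself. Independent lists would share 22.9 higher and 31.9 lower genes. Simulated unchanged groups shared 0, which says little, as groups without change give few calls. A regrouping of the real libraries reached 336 genes, higher and lower together. Because the 3 shared KO_1E7 libraries were too few to divide, part of the excess may come from sharing them. Without KO_1E7 3 the counts against both references were 16 and 4, without KO_1E7 1 they were 29 and 15, and without parental 1 they were 60 and 40. Without parental 2 or 3 they were 128 and 142 or 147 and 169, and without CRISPR_1G2 1 or 2 they were 161 and 140 or 153 and 136. Without KO_1E7 2 they were 215 and 317, and without CRISPR_1G2 3 they were 579 and 583. Any difference among the 3 groups was called for 1347 genes, against 126 without KO_1E7 3, 226 without KO_1E7 1, 848 without KO_1E7 2, 671 without parental 1, 504 and 582 without CRISPR_1G2 1 and 2, and 1983 without CRISPR_1G2 3.

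CRISPR_1G2 against parental served as the control for editing and cloning as far as the label wild type holds. If the clone comes from the knockout cells, as the design text of the series counts it, the contrast is no such control. It showed a small set of strong decreases. Among the 10 lowest genes under the fixed rule were Tnc, Lgals7, Thbs2, the lysosomal hexosaminidase gene Hexa (-5.05), Foxp2 (-5.05), Igsf3 (-5.00), the dystrophin gene Dmd (chromosome X, -4.67), Rasef (-4.06) and Il33 (-3.79). Tnc fell from 130 ± 51.7 CPM in parental to 2.07 ± 0.65 in CRISPR_1G2 (-5.96 ± 0.40, adjusted p = 0.000390). The galectin gene Lgals7 (chromosome 7, 28863853 to 28866284) fell from 35.5 ± 8.72 to 0.998 ± 0.39 CPM (-5.14), and Thbs2 from 305 ± 36.1 to 9.06 ± 3.26 CPM (-5.07 ± 0.31, adjusted p = 0.000335). Thbs2, Dmd and Igsf3 were also called higher in KO_1E7 than in parental (3.27, 1.87 and 1.36), while Tnc (0.32 ± 0.32, adjusted p = 0.583) and Hexa (0.24 ± 0.31, adjusted p = 0.694) were not. By edgeR 40 genes were lower and 0 higher. With an unadjusted p below 0.05 there were 522 higher and 696 lower genes, against 788.3 in all by chance, and DESeq2 called 69 higher and 166 lower. All 40 showed no overlap between groups, as did 13.1% of all genes where chance gives 10%.

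With the replicate number as a block, though only the third libraries clearly paired, 1 gene was higher and 36 were lower in CRISPR_1G2. The count of lower genes without the block was 19 without KO_1E7 1 or KO_1E7 3, 26 without KO_1E7 2, 15 without CRISPR_1G2 1 and 18 without CRISPR_1G2 2. Higher genes numbered 42 without parental 1 and 4 without KO_1E7 2. Of 14 called genes followed, 8 passed in all 9 fits that left out a library, among them Dmd, Hexa, Igsf3, Lgals7, Rasef, Thbs2 and Tnc. Hspg2 passed in 8, Foxp2 in 6, Axl in 5, Mtap in 4, Bgn in 2 and Il33 in 1, and as few as 9 passed without CRISPR_1G2 1 or without CRISPR_1G2 2.

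Of the gene lists, 6 of 27 passed for CRISPR_1G2 against parental. Collagen and matrix had 4 of 39 lower, namely Thbs2, Tnc, Hspg2 and the biglycan gene Bgn (-2.56 ± 0.36, adjusted p = 0.0287), and 2 higher and 7 lower over the list alone. The collagen and matrix test pointed down (adjusted p = 0.0460, or adjusted p = 0.684 with an estimated correlation) with a mean of -0.18, but the median was 0.31, as 26 of 39 estimates were positive. With the block the adjusted p was 0.244 for collagen and matrix and 0.0576 for Bgn. Without parental 1, KO_1E7 3, CRISPR_1G2 1 or CRISPR_1G2 3 that of collagen and matrix was 0.109, 0.0842, 0.473 or 0.281. For collagen and matrix it was 0.282 without the third library of each group, 0.1087 with parental 3 and CRISPR_1G2 3 left out and 0.195 with KO_1E7 2 out as well. Interferon-stimulated genes moved down (adjusted p = 7.75e-11, or adjusted p = 0.697 with an estimated correlation), with a median of -0.999 and 36 of 38 estimates negative. Of them 0 were called in edgeR or over the list alone. Isg15 stood at 23.2 ± 18.4 CPM in parental and 8.21 ± 1.98 in CRISPR_1G2 (-1.50 ± 0.50, adjusted p = 0.515). Summed CPM of interferon-stimulated genes was 738, 461 and 1748 in parental against 323, 579 and 722 in CRISPR_1G2, and with parental 3 and CRISPR_1G2 3 left out the median was -0.52 and the adjusted p 0.00112.

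The p53 targets moved up in CRISPR_1G2 (adjusted p = 0.000307, or adjusted p = 0.698 with an estimated correlation), with a median of 0.58 and 21 of 23 estimates positive. In edgeR 0 were called, and over the list alone 1 was higher, the death receptor gene Tnfrsf10b (0.76 ± 0.12). Summed CPM of p53 targets was 1942, 1649 and 4684 in parental 1, 2 and 3 and 2231, 2640 and 9034 in CRISPR_1G2 1, 2 and 3. Without CRISPR_1G2 3 the p53 targets had a median of -0.18 and an adjusted p of 0.937, and without parental 3 and CRISPR_1G2 3 a median of 0.30 and an adjusted p of 2.95e-06. The list ATF4 and amino acid response moved down (adjusted p = 0.000291, or adjusted p = 0.698 with an estimated correlation), with 24 of 27 estimates negative and 0 called in edgeR. Cebpb was lower over the list alone (-1.20 ± 0.25, adjusted p = 0.184). Without parental 1 the adjusted p of ATF4 and amino acid response was 0.118. Cytosolic ribosomal proteins moved down slightly (median -0.12, adjusted p = 0.0370, or adjusted p = 0.698 with an estimated correlation), with 30 of 36 estimates negative. Of these genes 0 were called in edgeR or over the list alone, and Rps6 stood at -0.34 ± 0.14. That call for cytosolic ribosomal proteins ended without parental 1 (0.109), parental 2 (0.266), KO_1E7 3 (0.0506), CRISPR_1G2 2 (0.1002) or CRISPR_1G2 3 (0.172). With the block, ERK pathway feedback genes (adjusted p = 0.0549 without it) and glycolysis and hypoxia (0.149) passed as well, at 0.0307 and 0.0339.

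Of the other lists, Il33 was the 1 gene lower of 25 in chemokines and cytokines and Axl, a receptor tyrosine kinase gene, the 1 lower of 16 in YAP and TEAD targets (-1.02 ± 0.12, adjusted p = 0.0129). All others had 0 called in edgeR, cAMP and PKA machinery (0 of 32, adjusted p = 0.837) and CREB-induced and immediate early genes (0 of 23, 0.837) among them. Over the list alone, 1 was lower in cAMP and PKA machinery, where the median was 0.06 and the mean -0.13, and 2 were lower in mesenchymal markers, where they were 0.12 and -0.02. By chromosome, 5 of 20 passed, namely 19 (-0.24, adjusted p = 2.19e-08), 3 (-0.10) and 14 (0.11), which also passed with an estimated correlation, and 16 (0.14) and X (0.13), which did not (0.185 and 0.349). Without CRISPR_1G2 1 only 2 passed, with chromosomes 3 and X at 0.0763 and 14 at 0.0587. Chromosomes 3 and X also ended with parental 3 and CRISPR_1G2 3 left out (0.0507 and 0.118) and with KO_1E7 2 out as well (0.0603 and 0.0705). They ended too without parental 3 (0.173 and 0.412), 14 without parental 2 (0.102) and 16 without CRISPR_1G2 3 (0.0787).

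**Figure D5:**
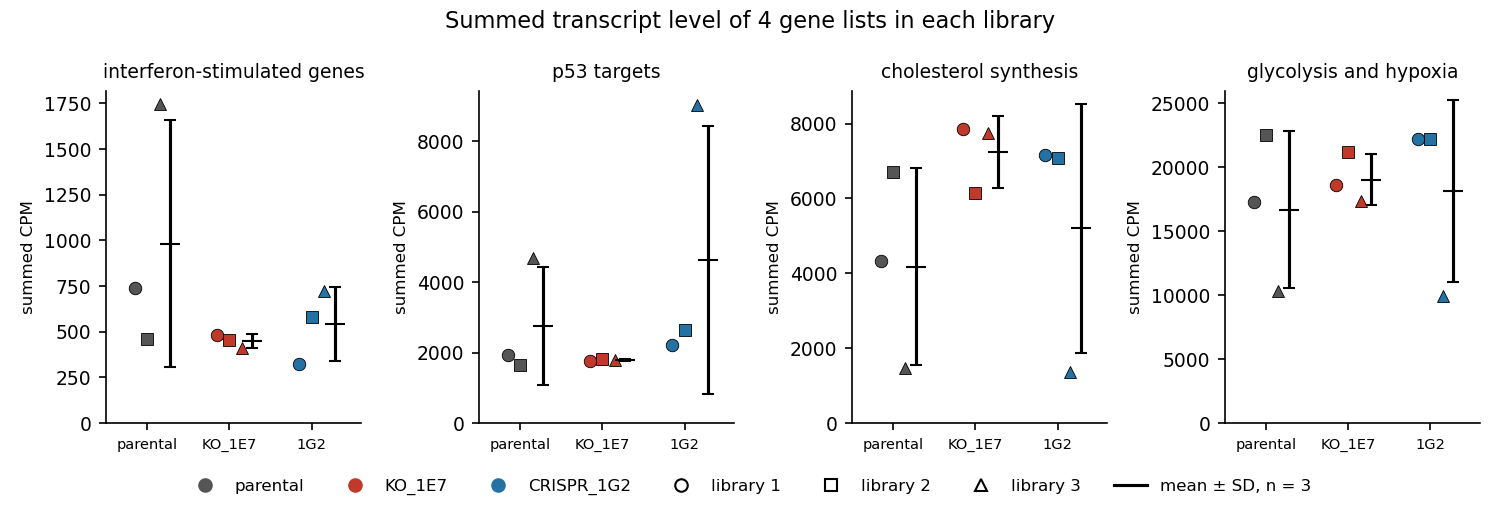
Summed CPM of interferon-stimulated genes, p53 targets, cholesterol synthesis genes and glycolysis and hypoxia genes in each of the 9 libraries, with points for libraries and bars for the mean and SD of each group. The p53 targets reached 4684 in parental 3 and 9034 in CRISPR_1G2 3, and cholesterol synthesis stood there at 1465 and 1362.

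Both clones against parental shared 0 higher and 6 lower genes by edgeR, and DESeq2 gave 15 higher and 37 lower. Hspg2 stood at 18.7 ± 1.41 CPM in parental, 2.27 ± 0.68 in KO_1E7 and 3.66 ± 0.68 in CRISPR_1G2 (-3.05 ± 0.26 and -2.35 ± 0.25). Mtap, the methylthioadenosine phosphorylase gene (chromosome 4, 89137122 to 89181081), stood at 27.3 ± 3.13, 4.77 ± 0.51 and 4.63 ± 2.20 CPM (-2.52 ± 0.33, adjusted p = 0.0111, and -2.56 ± 0.33, adjusted p = 0.0217). Hspg2 and Mtap were the only pair of the 6 that met the rule for named genes. The fold changes of the clones correlated across genes at 0.0692 (covariance 0.0362), where simulated unchanged groups, all libraries drawn anew, gave 0.497 (covariance 0.102). Both values lay below the simulated ones, and 51.1% of genes had the same sign in both clones against 66.4% simulated. The simulation drew libraries independently, while parental 3 and CRISPR_1G2 3 deviated together (correlation 0.647 across genes), which can lower the covariance. Across all genes no shared departure of the clones was seen above the simulated level, but this comparison cannot exclude one. Independent lists would share 1.15 lower genes, against the 6 seen, and simulated unchanged groups shared 0. The 3 shared parental libraries were too few to divide, so part of that excess of lower genes may come from them. Higher genes numbered 41 without parental 1, and lower genes 4 without parental 1, 3 without KO_1E7 1, KO_1E7 3 or CRISPR_1G2 2 and 2 without CRISPR_1G2 1.

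Markers of cell types other than the tumour line were low. Of 13 tested immune cell markers, 0 passed in edgeR or over the list alone. The list moved up in both clones against parental (KO_1E7 adjusted p = 0.0194, or adjusted p = 0.818 with an estimated correlation, and CRISPR_1G2 adjusted p = 1.41e-06, or adjusted p = 0.684 with an estimated correlation). Summed CPM for immune cell markers was 31.3, 4.67 and 17.6 in parental 1, 2 and 3, 28.1 to 30.2 in KO_1E7 and 25.2 to 41.2 in CRISPR_1G2. The low library was parental 2, and without it the adjusted p for immune cell markers was 0.195 in KO_1E7. Without parental 3 and CRISPR_1G2 3 it was 0.114 in KO_1E7 and 0.00274 in CRISPR_1G2. In KO_1E7 the adjusted p for immune cell markers was 0.131 without the third library of each group and 0.251 without parental 3, CRISPR_1G2 3 and KO_1E7 2. Lysozyme gene Lyz2 stood at 12.4, 0.525 and 2.39 CPM in parental 1, 2 and 3, at 14.7, 13.2 and 13.5 in KO_1E7 and at 18.8, 10.6 and 14.2 in CRISPR_1G2. Ptprc, the gene of the leukocyte antigen CD45, stood at 1.97, 0.0276 and 0.0834 CPM in parental, 1.84, 2.56 and 1.88 in KO_1E7 and 3.85, 2.175 and 2.53 in CRISPR_1G2. Adgre1, the gene of the macrophage marker F4/80, stayed at or below 0.509 CPM in every library.

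Pancreatic duct markers, which the tumour line itself expresses, summed to 3652, 4281 and 2739 CPM in parental, KO_1E7 and CRISPR_1G2. In KO_1E7 against parental 2 of 10 duct markers were lower (3 over the list alone, adjusted p = 0.0552), Krt7 and the carbonic anhydrase gene Car2 (-3.89 ± 0.60). Both were also lower against CRISPR_1G2 (adjusted p = 0.502 for the list). Fibroblast markers summed to 113, 166 and 105 CPM, with 0 of 8 called in KO_1E7 against parental in edgeR (adjusted p = 0.0818). Against CRISPR_1G2 Pdgfrb and Col1a2 were higher and Col1a1 lower (adjusted p = 0.502 for fibroblast markers). Endothelial markers summed to 6.20, 4.48 and 6.04 CPM, with 0 of 6 called (adjusted p = 0.427, 0.837 and 0.724 in KO_1E7 against parental, CRISPR_1G2 against parental and KO_1E7 against CRISPR_1G2). Acinar markers summed to 3.21, 11.1 and 2.31 CPM with 2 tested, of which the elastase gene Cela1 rose in KO_1E7 (2.23 ± 0.35 against parental and 2.94 ± 0.37 against CRISPR_1G2). Islet markers (1.23, 0.746 and 0.992 CPM, Mafa tested) and erythroid markers (1.33, 0.994 and 1.38 CPM, Alas2 tested) had 1 gene tested each and 0 called in edgeR.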

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

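Of the tests in this part, those of ribosomal RNA and of a shared batch for parental 3 and CRISPR_1G2 3, and all 3 for KO_1E7 2 (mixed cells in its lower genes, mixed cells in its higher genes and a wrong label), were chosen after the result was seen.

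The clones differed in how they departed from parental. The difference between the departures is the contrast of KO_1E7 against CRISPR_1G2 given above, not a further test. It was called for 901 genes that were higher in KO_1E7 than in CRISPR_1G2 and for 1109 that were lower. Thbs2 rose in KO_1E7 (3.27) and fell in CRISPR_1G2 (-5.07). Spike-in controls, data outside the gene counts, took 0.344% of counts in parental 3, the lowest library, and 0.820% in KO_1E7 1, the highest, above the limit that a count of 0 allows. They were not used for scaling.

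Parental 3 and CRISPR_1G2 3 lay apart from the other libraries of their groups, with p53 targets high and cholesterol synthesis genes low by a combined 3.16 and 4.37 on the log2 scale. Carried-over ribosomal RNA, high in parental 3, was argued against as the common source by a share of only 1.12% in CRISPR_1G2 3. A batch shared by the libraries numbered 3 could be neither shown nor excluded. KO_1E7 3 shared the word in its deposited name but deviated by -0.19. Its deviations correlated with those of parental 3 and CRISPR_1G2 3 at 0.153 and 0.0727, against 0.647 between these. As KO_1E7 3 comes from a clone that may respond differently to a batch, its values cannot decide. Removing the trend with gene length and GC content left 94.6% and 99.0% of the deviation. A state of stressed cultures in these libraries may remain as a hypothesis, but the labels describe no treatment or density, so no biological explanation was tested.

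KO_1E7 2 lay between the other KO_1E7 libraries and the references. At 39 genes at least 8-fold lower in KO_1E7 1 and 3 than in every reference library, the level in KO_1E7 2 implied a median share of 27.0% reference cells. Of these genes 89.7% lay within 2-fold of that median (79.5% against parental alone), with implied shares from 8.98% to 45.7%. Thus 1 admixed share of cells without the KO_1E7 state may account for most of the lower genes. At 10 genes at least 8-fold higher in KO_1E7 1 and 3, the implied median was 84.1% (15.8% to 95.5%). This share lay far from that of the lower genes, so 1 mixture could not account for the higher genes. The shifts of chromosomes 7, 8, 16 and 14 in KO_1E7 2 were 62.9%, 76.1%, 70.98% and 98.7% of the mean of KO_1E7 1 and 3. That of chromosome 14 was hardly reduced, unlike the others, so these shifts do not settle whether cells were mixed. A wrong label on the library was argued against by its correlations with KO_1E7 1 and 3, the lower being 0.983, above its highest with any reference library (0.975). What separates KO_1E7 2 from its group at the higher genes stays open, and drift within the clone was not tested.

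Genes of whole chromosomes shifted together in KO_1E7, chromosome 7 by -0.42 on the log2 scale. The shift of chromosome 7 was spread over most of its genes, as 80.6% of those tested lay below the median of all genes. Without the called genes 88.6% of the shift was left, but a median hardly responds to a few strong genes, so this check could not decide. Gene length and GC content were argued against as the source, with 91.97% left after their trend was removed. A different number of chromosome copies in the clone may underlie the shifts, as 100% of the 26 bins of 20 Mb on chromosomes 7, 8, 14 and 16 lay on the side of their chromosome, a test that could have come out otherwise. The shift was uneven on chromosome 16, with medians of -0.43 and -0.44 in the bins up to 40 Mb, -0.12 at 40 to 60 Mb, -0.05 at 60 to 80 Mb and -0.24 beyond, so a change of the whole chromosome need not hold there. The other shifted chromosomes (2, 9, 11 and 13) were not divided into bins. No copy number was measured, and this remains a hypothesis found and tested on the same data.

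Regrouping the 6 libraries of a pair of groups gives 10 splits, too few for a share under 0.05. For KO_1E7 against parental the real split called 854 genes and the highest other 0 (1 split as large, the real one), with 7 lists against 13 (9 splits as large) and 8 chromosomes against 10 (2 splits as large). For KO_1E7 against CRISPR_1G2 it called 2010 genes against 0 (1 split), 2 lists against 11 (10 splits) and, adjusted within that comparison, 12 chromosomes against 8 (1 split). For CRISPR_1G2 against parental it called 40 genes against 817 (2 splits), 6 lists against 11 (9 splits) and 5 chromosomes against 3 (1 split). In every comparison other splits passed at least as many lists as the real one. The number of list calls thus cannot be told from that of other arrangements of these libraries. The same holds for the number of chromosomes passing in KO_1E7 against parental, 8 against 10 in another split. The split with 817 set parental 2, CRISPR_1G2 1 and CRISPR_1G2 2 against parental 1, parental 3 and CRISPR_1G2 3 and points to a structure of the samples other than the clone. Among the 4 splits that part all 3 pairs of same-numbered libraries there, the other 3 called 0 genes. Of 100 splits of all 9 libraries, the real one alone reached 1347 genes for any difference among groups (highest other 327) and 706 for KO_1E7 against both references (336), so a chance arrangement of the libraries can be excluded for these counts at a share of 0.05. The split with 327 and 336 kept the KO_1E7 libraries together and mixed the others. The 6 genes of both clones against parental were reached by 4 splits (highest other 36). The 3 others among them set parental 1, parental 3 and CRISPR_1G2 3 together, as the split with 817 did, so this structure of the samples can give as many genes and the count is left open. With the replicate number as a block, 6 genes were lower in both clones. Among the 48 of the 100 splits that part all 3 pairs of same-numbered parental and CRISPR_1G2 libraries, a comparison added after the result was seen, the real one alone reached each of the 3 counts (highest others 327, 336 and 4). As only the third libraries clearly paired, neither restriction to splits that part the pairs settles the counts of 40 and 6 genes.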

How the results depend on the processing

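Alternatives with parental 3 and CRISPR_1G2 3 left out, with KO_1E7 2 left out as well and with voom quality weights, and the recomputation of lists, chromosomes and genes near Vipr2 without each library, were chosen after seeing the data. Counts are given as higher and lower genes, in the order KO_1E7 against parental, CRISPR_1G2 against parental, KO_1E7 against CRISPR_1G2, any difference among the groups, KO_1E7 against both references and both clones against parental. Counts not given for a setting moved by at most 1.5 times, and the cause was not tested unless stated. DESeq2 size factors moved no count that far and changed no call of a list, chromosome or named gene. With DESeq2 the counts were 1091 and 1267, 69 and 166, 1527 and 1847, 3298, 844 and 962, and 15 and 37. DESeq2 gave no adjusted p for Zfp110 and Renbp in KO_1E7 against CRISPR_1G2, and lists and chromosomes have no DESeq2 value. With no filter on low counts, which tests more genes, lower genes were 271 in KO_1E7 against parental, 731 against CRISPR_1G2 and 200 against both references, and 3 were higher in CRISPR_1G2 against parental. With at least 1 CPM in 3 libraries, 2 genes were higher in CRISPR_1G2 against parental and 1 in both clones. With only the groups compared, which leaves fewer samples, CRISPR_1G2 against parental had 2 and 14, and both clones 3 lower.

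With the replicate block, lower genes were 709 in KO_1E7 against parental and 573 against both references, and 1 gene was higher in CRISPR_1G2 against parental. KO_1E7 shares replicate numbers with the other groups. In the deposited names KO_1E7 1 also shares a date with parental 1, and KO_1E7 3 the word NSG with parental 3 and CRISPR_1G2 3. Parental 2 shares a date with CRISPR_1G2 1, whose number differs. For KO_1E7 the correlations were weak. Not every pair of same-numbered libraries correlated above 0.1 (-0.00, 0.06 and 0.15 to parental, and -0.05, 0.13 and 0.07 to CRISPR_1G2), and not every library correlated best with its own number. The block added proliferation (adjusted p = 0.0468), p53 targets (0.0447) and endoplasmic reticulum chaperones (0.0457) in KO_1E7 against parental and cholesterol synthesis (0.0178) in KO_1E7 against CRISPR_1G2. Stc2 (0.0525), Col1a1 (0.0591) and Col1a2 (0.0591) no longer passed against CRISPR_1G2, with ranges over all settings of 0.00210 to 0.160, 0.00334 to 0.10003 and 0.000897 to 0.168. Bgn in CRISPR_1G2 against parental ranged from 2.22e-09 to 0.179. In CRISPR_1G2 against parental the block changed no call but those given beside the results.

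With a term for the word NSG the counts were 956 and 1104, 5 higher, 1550.0 and 1780.0, 2676, 775 and 847, and 1 higher in both clones, and Vipr2 in KO_1E7 against CRISPR_1G2 passed (adjusted p = 0.0481). It also passed with DESeq2 (0.0458) and without CRISPR_1G2 1 (0.0368), while over all settings its adjusted p ranged from 0.0368 to 0.202. With the date or word as a factor they were 815 and 1040.0 in KO_1E7 against parental, 4 higher in CRISPR_1G2 against parental, 641 and 805 against both references and 3 lower in both clones. Vipr2 in CRISPR_1G2 against parental reversed there to -0.10 (adjusted p = 0.971). With parental 3 and CRISPR_1G2 3 left out they were 1540.0 and 1789, 4 higher, 2331 and 2284, 4260.0, 1240.0 and 1375, and 10 lower in both clones. With KO_1E7 2 out as well they were 1981 and 2440.0, 171 and 155, 2675 and 2882, 5264, 1631 and 2018, and 11 and 34. With voom quality weights they were 2292 and 2703, 483 and 600.0, 3110.0 and 3287, 6632, 1780.0 and 2032, and 76 and 195. Such fits give little weight to libraries that stand apart (0.232 for parental 3 and 0.135 for CRISPR_1G2 3).

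Lists past the threshold numbered 0 in each comparison with an estimated correlation. In CRISPR_1G2 against parental 10 lists passed without the third library of each group and 11 without parental 3 and CRISPR_1G2 3, and in KO_1E7 against CRISPR_1G2 4 passed with KO_1E7 2 out too. In the window of 5 Mb around Vipr2, 2 genes passed in KO_1E7 against parental and 4 in KO_1E7 against CRISPR_1G2. Leaving out each library in turn, higher genes ranged from 16 to 953 and lower from 8 to 1045 in KO_1E7 against parental, from 0 to 42 and 15 to 33 in CRISPR_1G2 against parental, and from 273 to 1115 and 180.0 to 1217 in KO_1E7 against CRISPR_1G2. Any difference ranged from 126 to 1983, KO_1E7 against both references from 16 to 579 and 4 to 583, and both clones from 0 to 41 and 2 to 8. Vipr2 ranged from -2.80 to -1.80 in KO_1E7 and from 0.10 to 1.13 in CRISPR_1G2 against parental. In the same 3 comparisons lists ranged from 6 to 11, 4 to 11 and 1 to 4, chromosomes from 7 to 12, 2 to 5 and 10 to 12, and genes near Vipr2 from 0 to 1, 0 to 0 and 0 to 1.

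The ranges of list tests that follow do not include the replicate block. Over the other settings the adjusted p in KO_1E7 against parental ranged from 7.19e-23 to 0.818 for interferon-stimulated genes, 2.51e-07 to 0.818 for cholesterol synthesis, 1.65e-05 to 0.488 for epithelial markers and 1.65e-05 to 0.818 for ERK pathway feedback genes. It ranged from 7.50e-05 to 0.818 for ATF4 and amino acid response, 1.85e-14 to 0.818 for immune cell markers and 0.0105 to 0.818 for mitochondrially encoded mRNAs. In CRISPR_1G2 against parental it ranged from 6.19e-25 to 0.697 for interferon-stimulated genes, 1.58e-08 to 0.937 for p53 targets, 9.12e-09 to 0.698 for ATF4 and amino acid response and 0.00360 to 0.684 for collagen and matrix. Cytosolic ribosomal proteins lay from 0.00192 to 0.698 and immune cell markers from 2.09e-32 to 0.684. In KO_1E7 against CRISPR_1G2 epithelial markers lay from 6.17e-07 to 0.480 and p53 targets from 1.60e-06 to 0.996.

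Over these settings, the replicate block not counted for lists and chromosomes, called lists kept their call in 163 cases and lost it in 47, and chromosomes in 293 and 19. Named genes kept their side in 2947, lost it in 564 and gained it in 26, with 0 reversed in sign among called genes. Depth limits the low genes most, as Vipr2 with at most 13 counts per library and Vip with at most 19 allow no firm statement.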

Other observations

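Of the tests in this part, those on parental between the clones, on the neighbours of Mtap and on zinc finger genes were fixed before their results were seen, although the patterns that prompted them had been noticed in the data.

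Some genes outside the named-gene rule, chosen after their values were seen, differed strongly between libraries of KO_1E7. Serpinh1, the collagen chaperone gene, stood at 8.34, 131 and 4.78 CPM in KO_1E7 1, 2 and 3 against 294 ± 67.0 in parental and 408 ± 82.2 in CRISPR_1G2, and it did not pass in KO_1E7 against parental (adjusted p = 0.179). Ifitm1 stood at 5.03, 125 and 2.09 CPM there. Capn6, in contrast, was even across KO_1E7 1, 2 and 3 at 4.69, 3.92 and 4.597 CPM, against 0.119 ± 0.03 in parental and 0.0204 ± 0.04 in CRISPR_1G2 (5.16 ± 0.55 against parental, adjusted p = 0.00526). Thbs2 was also even, at 2756, 3399 and 2658 CPM in KO_1E7 1, 2 and 3.

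Single genes chosen after their values were seen, a choice that tests no class of genes, were highest in parental 3 and CRISPR_1G2 3. Txnip reached 281 and 458 CPM there against 6.101 to 22.4 in the other 7 libraries. Plk2 reached 645 and 778 CPM against 29.9 to 76.9, Atf3 137 and 130.4 against 7.37 to 27.6, and Gdf15 206 and 132 against 2.33 to 68.9, the last in parental 1. Summed CPM of CREB-induced and immediate early genes was 1913 and 1753 in these libraries and 704 to 1133 in the others, proliferation genes stood at 4823 and 5504 against 7483 to 9574, and glycolysis and hypoxia genes at 10293 and 9900 against 17283 to 22503.

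At genes that differed strongly between the clones, parental often lay between them. Among 502 genes called at 4-fold or more between KO_1E7 and CRISPR_1G2, the parental mean lay between for 442 (88.0%), while CRISPR_1G2 lay between for 84 of the 204 genes (41.2%) called at 4-fold or more in KO_1E7 against parental, a gap of 46.9 percentage points. Thbs2, at 305 ± 36.1 CPM in parental, 2937 ± 403 in KO_1E7 and 9.06 ± 3.26 in CRISPR_1G2, is an example. With the departures of CRISPR_1G2 shuffled across genes, a check added after the result was seen, the shares were 69.8% and 46.7% and the gap 23.1 points. Choosing genes by their difference between the clones thus gives part of the gap by itself, past the limit of 20 points set beforehand, so that limit could not decide. The source of the rest of the gap was not tested and stays open.

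Mtap was lower in both clones, and it lies near Cdkn2a and Cdkn2b on chromosome 4, a stretch often lost in tumour lines. The hypothesis of a lost stretch around Mtap was argued against in KO_1E7, where the 16 tested genes within 2 Mb had a median log2 fold change of 0.25, with 0 lower and 2 higher. In CRISPR_1G2 their median was -0.65 with 0 called, and a loss there could be neither shown nor excluded. Zinc finger genes stood among the lowest of KO_1E7 (Zfp503, Zfp850, Zfp110), and the hypothesis that they fell as a class was argued against outside chromosome 7, where 236 of them lay 0.13 above the median of all genes with 3 lower and 6 higher. On chromosome 7 itself, 20 of 80 were lower and their median was -0.54 relative to all genes.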
